A study of Homo sapiens with 4 samples.

How the data were processed

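The authors deposited 1 table of raw counts per gene symbol, with 1 column for each of the 4 libraries. Per the labels' protocols, A549 cells in 6-well plates were transfected with Lipofectamine iMAX, total RNA was extracted with Trizol at 24 h, RNA of sufficient integrity was kept, and libraries were sequenced on the Ion Proton. The submitters' processing notes name the genome build GRCh37; the aligner, the counting program, the annotation and the use of strand are not given in the sources used here. Without them, reads shared by near-identical copies, and reads of overlapping genes on opposite strands, may have been assigned in ways that cannot be traced from the counts. The deposited counts were whole numbers and were used as they stood. The table held 40205 symbols, of which 14572 had no count in any library; 0 entries named no gene, and 0 columns belonged to no sample.

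The groups were taken from the sample titles: 2 libraries with control siRNA and 2 with siRNA to SBF2-AS1. Replicates were compared before averaging. The chi-square per gene was 3.95 between the controls and 3.61 between the knockdown libraries, above the value of 1 that counting noise gives, so no library was a copy of another; between groups it was 49.3 to 55.0. With 12149767 to 12938143 counts per library the coefficient of biological variation was 6.64%. Exact Poisson 95% intervals for SBF2-AS1 cover counting error only.

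Groups were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, robust quasi-likelihood fits (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment at 0.05 over the genes tested. CPM values are TMM-scaled, and those of the checks for other cell types are scaled by library size. SE is the log2 fold change divided by the root of the F statistic. A fit with 3 groups (controls, Knockdown-670, Knockdown-732) gave the single-library comparisons, with its residual spread from the control pair only. The 31 gene lists fixed before the data were examined were tested, where at least 5 members were expressed, with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 27 lists. With an estimated correlation 0 of the 27 lists passed (5 at an unadjusted p under 0.05), and with fry, which asks only whether members move on balance in one direction, 22 passed. The estimated correlation rests on 2 libraries per group, so that test has little power, and a lost call does not show that a shift was absent. The lists cover replication and E2F, mitosis, p53 targets, interferon response, ATF4 and unfolded proteins, cholesterol, mesenchymal, epithelial, NRF2, hypoxia and glycolysis, NF-kB, immediate early and stress, ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation, histones, TGF-beta, WNT, YAP, RNA silencing, polycomb, 11p15 neighbours, SBF2-AS1 literature, abundant long non-coding RNAs, alveolar and secretory epithelium, fibroblast, immune, endothelial and erythroid markers, apoptosis, and autophagy and lysosome.

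The genes to be named were set by rule: SBF2-AS1 and SBF2; among genes past the threshold with non-overlapping libraries and a mean of at least 5 CPM, the 15 with the largest rise and the 15 with the largest fall; and up to 4 called members of smallest p from each list. Ribosomal, mitochondrial and pseudogene symbols were named only through a list. Some genes that the rule takes are not reported here. UHRF1, PFKM, VIM, ZEB1, ITGAV, AJUBA, GADD45B, JARID2, OAS1, OAS3, ESAM, PTPRC, LYZ, HLA-DRA, CD14, ITGAM, SFTPB, SCGB1A1, NKX2-1 and the interferon genes were named after their values were seen, as were further genes that the closing section marks so.

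Reference annotation was GENCODE v29 on GRCh38, which is not the build of the authors; the count table holds no coordinates, so it was joined by symbol. Of the symbols, 28572 matched directly, 1288 through a synonym in a RefSeq table of GRCh38.p14 and 10345 not at all. The longest annotated 3' UTR of each gene, if at least 50 bases, was searched for matches to bases 2 to 8 of each microRNA, whose sequences were taken from memory. Simulated counts with 200 changed genes tested the scripts: 55.2% of 1.5-fold, 82.1% of 2-fold and 95.5% of 4-fold changes were called among 15682 genes, and 10.9% of the 174 calls were unchanged genes, above the nominal rate. In a set of 30 simulated lists camera called the shifted one and 0 of 29 others. The genes were simulated independently, so this does not show how often camera calls lists of correlated genes wrongly.

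Alternatives were DESeq2 size factors, upper-quartile scaling, library size only, no filter, a filter of 5 CPM in at least 2 libraries, each library left out in turn, DESeq2 1.42.0, limma-voom, edgeR's exact test, a non-robust fit, glmTreat against 1.2-fold and an adjusted p of 0.1; the closing section gives their effect on the number of genes called. A correction for transcript GC content and length, a run without pseudogenes and unmatched symbols, and lists without genes holding the heptamer described in the closing section were added after the data were seen. The median log2 fold change of tested genes was -0.002, and no scaling moved it by more than 0.0629.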

Results

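The data were RNA-seq counts of 4 libraries from A549, a human lung adenocarcinoma cell line, harvested 24 h after transfection with small interfering RNA (siRNA). In 2 libraries the siRNA was a negative control (control libraries 1 and 2), and in 2 it was directed at SBF2-AS1, a long non-coding RNA (libraries Knockdown-670 and Knockdown-732, numbers whose meaning the labels do not give). The libraries held 12701132 and 12938143 counts in the controls and 12149767 and 12894529 in the knockdown, over 22025 to 22419 genes with a count. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

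The level of SBF2-AS1 itself was read first. SBF2-AS1 fell from 5.19 ± 1.11 CPM (counts scaled to TMM-adjusted library size; SD, n = 2) in the controls to 1.35 ± 0.10 CPM (SD, n = 2) in the knockdown, 74.1% lower, with counts of 57 and 79 against 15 and 18. The log2 fold change was -1.94 (SE 0.30, edgeR adjusted p = 3.19e-05). The exact Poisson 95% intervals, which cover counting error only, were 3.34 to 5.71 and 4.73 to 7.44 CPM in the controls and 0.713 to 2.10 and 0.841 to 2.24 CPM in libraries Knockdown-670 and Knockdown-732. SBF2-AS1 is annotated in GENCODE on GRCh38 as an antisense gene on the + strand of chromosome 11, from 9758292 to 9811335, with 7 transcripts of 2 to 5 exons, the longest of 3693 nt. It overlaps SBF2, a protein-coding gene on the - strand from 9778667 to 10294207. SBF2 rose from 110 ± 5.17 to 139 ± 3.42 CPM (SD, n = 2 each), a log2 fold change of 0.34 (SE 0.07, edgeR adjusted p = 0.000872). Whether the counting used strand is not given in the sources used here, so reads of this overlapping pair may have been exchanged. Since SBF2-AS1 fell, its reads counted as SBF2 would lower SBF2, so exchange in that direction does not account for the rise.

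**Figure D1:**
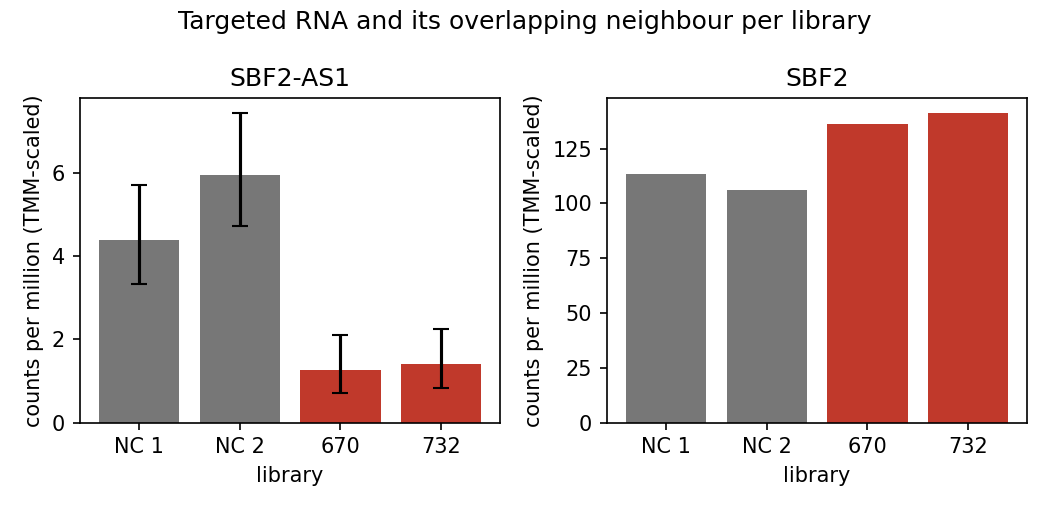
SBF2-AS1 (left) and SBF2 (right) in CPM after TMM scaling, a bar for each library, controls in grey and knockdown in red; error bars on the left are exact Poisson 95% intervals of the count. SBF2-AS1 lay at 4.41 and 5.97 CPM in the controls and at 1.27 and 1.42 CPM in the knockdown libraries.

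The comparison that the labels state was siRNA to SBF2-AS1 against control siRNA. Of the 27 lists tested in camera, the interferon response had the highest median log2 fold change (2.66) and mitosis the lowest (-1.61). Both calls were lost with an estimated correlation (adjusted p = 0.119 for each). That correlation was estimated from 2 libraries per group, and 0 of 27 lists passed, so the test has little power to decide. Of 16120 genes tested, 7463 (46.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3785 higher and 3678 lower in the knockdown. The balance turned with library size only, 3243 higher and 4265 lower, with a correction for GC content and length, 3160 and 3515, and without Knockdown-732, 3358 and 3391. At least a 2-fold change was seen for 898 of the higher and 746 of the lower genes. Over all tested genes, both knockdown libraries lay on the same side of both controls in 72.6%, where chance gives 33.3%. Tested against a fold change of 1.2 instead of no change, 4680 genes passed, 2451 higher and 2229 lower. On simulated counts with the same number of libraries, 10.9% of the 174 calls among 15682 genes were unchanged genes, above the nominal rate. Far fewer genes were changed in that simulation than were called here. Its share therefore does not give the share of unchanged genes among the 7463 calls.

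Among called genes with a mean of at least 5 CPM, the 15 with the largest rise were IFIT1, OAS2, MX1, CMPK2, ISG15, IFI27, OASL, IFI44L, IFIT2, IFI6, IFIT3, IFI44, SAMD9, CCL5 and APOL1. IFIT1, an antiviral protein that binds foreign RNA, went from 4.82 ± 0.726 to 145 ± 5.12 CPM (SD, n = 2 each; log2 fold change 4.91, SE 0.11, edgeR adjusted p = 4.48e-16). MX1, an antiviral GTPase, went from 9.75 ± 0.535 to 221 ± 1.65 CPM, 22.7-fold. ISG15, a ubiquitin-like protein, rose 21.7-fold from 9.67 ± 0.115 CPM, and the chemokine CCL5 rose 9.36-fold from 10.5 ± 0.642 CPM. APOL1, last of the 15, rose 8.08-fold.

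All 37 tested members of the interferon response list rose, over all genes and adjusted over the list alone, with a median log2 fold change of 2.66 (6.31-fold). By library the median was 2.59 in Knockdown-670 and 2.70 in Knockdown-732, against 0.02 and -0.02 in the controls. The list differed from other genes in limma's camera test (adjusted p = 6.86e-21; adjusted p = 0.119 with an estimated correlation). OAS3, which makes the 2'-5' oligoadenylates that activate RNase L, rose 5.19-fold and OAS1 5.90-fold. The interferon genes themselves were near the counting floor: IFNB1 had 0 and 0 counts in the controls and 2 and 4 in libraries Knockdown-670 and Knockdown-732, and IFNL1 had 2, 0, 3 and 2 in the same order.

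By the same limit of 5 CPM, which leaves out scarcer genes that fell more, the 15 genes with the largest fall were KIAA0101, SPDEF, HMMR, PBK, NEIL3, DEPDC1, EXO1, INSL4, ZNF367, ZWINT, CDKN3, FAM72D, PDE3A, SPC25 and MLF1IP. KIAA0101, a PCNA-binding protein, went from 27.1 ± 1.19 to 4.27 ± 0.757 CPM (SD, n = 2 each), a log2 fold change of -2.66 (SE 0.16, edgeR adjusted p = 2.51e-10). HMMR, a spindle protein, went from 69.6 ± 2.18 to 12.6 ± 1.47 CPM (log2 -2.46). The mitotic kinase PBK had a log2 fold change of -2.41 and the exonuclease EXO1 one of -2.30. SPDEF, an epithelial transcription factor, and INSL4, a relaxin-family peptide, are not cell-cycle genes and had log2 fold changes of -2.56 and -2.29. FAM72D belongs to a family of near-identical copies, so its count is uncertain.

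All 36 members of the mitosis list fell, with a median log2 fold change of -1.61 (camera adjusted p = 2.41e-19; adjusted p = 0.119 with an estimated correlation). The spindle factor TPX2 went from 239 ± 5.84 to 70.1 ± 1.56 CPM (log2 -1.77), topoisomerase TOP2A from 512 ± 0.906 to 163 ± 3.10 CPM (log2 -1.65) and the kinetochore protein CENPF from 201 ± 10.8 to 64.8 ± 0.797 CPM (log2 -1.64). In the replication and E2F list 37 of 38 members fell and none rose, with a median of -1.37 (camera adjusted p = 2.27e-17; adjusted p = 0.119 with an estimated correlation). RRM1, the large subunit of ribonucleotide reductase, fell by 1.98 on the log2 scale, DNA polymerase subunit POLA1 by 1.85, the helicase subunit MCM4 by 1.46 and thymidine kinase TK1 by 1.39. The exception was UHRF1, with a log2 fold change of -0.03 (edgeR adjusted p = 0.91). The counts of both lists were the same adjusted over the list alone.

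Of 35 hypoxia and glycolysis genes, 31 rose, 1 fell and 3 did not pass, the same adjusted over the list alone, with a median log2 fold change of 0.71 (camera adjusted p = 1.61e-11; adjusted p = 0.119 with an estimated correlation). NDRG1, induced by low oxygen, went from 393 ± 14.01 to 1491 ± 133 CPM (log2 1.92), the neuronal enolase ENO2 from 130 ± 7.27 to 407 ± 14.1 CPM (log2 1.65) and carbonic anhydrase CA9 from 32.0 ± 0.567 to 92.6 ± 1.41 CPM (log2 1.53). The aldolase ALDOC rose by 1.74 on the log2 scale, and the muscle phosphofructokinase PFKM fell by 0.33. Of 31 mesenchymal genes 19 rose, 3 fell and 9 did not pass, the same adjusted over the list alone (median 0.70, camera adjusted p = 4.95e-05; adjusted p = 0.199 with an estimated correlation). The collagen crosslinker LOXL2 went from 394 ± 14.1 to 1794 ± 74.6 CPM (log2 2.19), the kinase AXL from 254 ± 19.9 to 716 ± 17.5 CPM, and the integrin ITGA5 rose by 1.40 on the log2 scale. The 3 that fell were VIM (log2 -0.24), ZEB1 (-0.34) and ITGAV (-0.99), of which the intermediate filament VIM and the repressor ZEB1 are classical mesenchymal markers. Of 24 YAP targets 14 rose and 2, AJUBA and GADD45B, fell, with 16 higher and 2 lower adjusted over the list alone (median 0.41, camera adjusted p = 0.00304; adjusted p = 0.402 with an estimated correlation). Tissue factor F3 rose by 2.51, IGFBP3 by 1.31 and CRIM1 by 0.88 on the log2 scale. With the GC and length correction the YAP median was 0.23, with 12 higher and 5 lower.

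**Figure D2:**
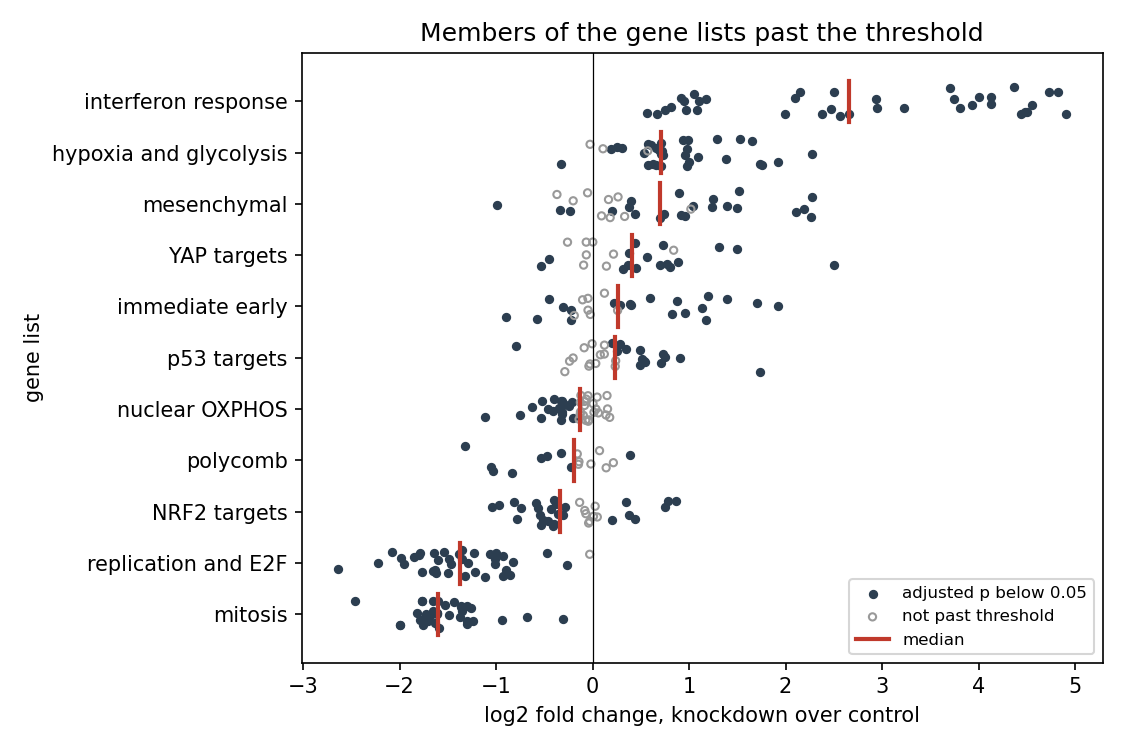
Log2 fold change, knockdown over control, of each tested member of the 11 gene lists past the camera threshold, one list per line; filled points passed edgeR's adjusted p of 0.05, open points did not, and the vertical bar is the list median. Medians ran from -1.61 for mitosis to 2.66 for the interferon response.

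NRF2 targets, the antioxidant genes that A549 expresses at a high level, fell in 19 of 34 cases and rose in 7, the same adjusted over the list alone (median -0.33, camera adjusted p = 0.0297; adjusted p = 0.384 with an estimated correlation). ALDH1A1 went from 5319 ± 483 to 2576 ± 145 CPM (log2 -1.05), ALDH3A1 from 2478 ± 44.1 to 1261 ± 44.5 CPM (log2 -0.97) and AKR1B10 fell by 0.81 on the log2 scale, while heme oxygenase HMOX1 rose by 0.75. Without library Knockdown-732 the list was at an adjusted p of 0.085 in camera (0.0105 to 0.384 over its 13 alternatives), 4 in place of 7 members rose without control library 2, and the median was -0.15 with the GC and length correction (5 higher, 15 lower). Of 40 nuclear genes of oxidative phosphorylation 18 fell and none rose, the same adjusted over the list alone (median -0.13, camera adjusted p = 0.0257; adjusted p = 0.563 with an estimated correlation), and the ATP synthase subunit ATP5B fell by 1.12 and the complex III subunit UQCRFS1 by 0.75 on the log2 scale. That call was lost without control library 1 (camera adjusted p = 0.0815), without library Knockdown-732 (0.0732) and with a correction for GC content and length (0.274), with a range of 0.00566 to 0.563 over 13 alternatives. The 18 fallen members became 10 without Knockdown-732, 12 (and 1 higher) without control library 1, 11 in DESeq2 and 15 (and 5 higher) with the GC and length correction, and the median was -0.26 without control library 2 and -0.22 without Knockdown-670. Mitochondrially encoded genes took 11.001 and 11.046% of the counts in the controls and 9.36 and 9.32% in libraries Knockdown-670 and Knockdown-732. Of those 15 genes 7 fell and none rose, the same adjusted over the list alone (camera adjusted p = 0.182), among them ATP8 (log2 -0.61), COX2 (-0.47) and the ribosomal RNA RNR2 (-0.43). In that list 2 genes rose with no filter on low counts and 1 in limma-voom. The list's median was -0.09 without control library 2, against -0.17 with all libraries and -0.29 without control library 1.

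Immediate early and stress genes rose in 14 of 27 cases and fell in 6, or 7 adjusted over the list alone (median 0.26, camera adjusted p = 0.0465; adjusted p = 0.384 with an estimated correlation). The heat-shock genes HSPA1A and HSPA1B, close copies whose reads may be split, rose by 1.93 and 1.70 on the log2 scale, the phosphatase DUSP5 by 1.19 and FOSL1 by 1.17. The call was lost without control library 1 (camera adjusted p = 0.0629), without library Knockdown-732 (0.0732) and with the GC and length correction (0.0889), with a range of 0.00432 to 0.384 over 13 alternatives. The 6 fallen members became 3 without control library 2, without Knockdown-670 and in DESeq2, and 4 without control library 1. Of 16 polycomb genes 8 fell and 1, JARID2, rose, the same adjusted over the list alone, and 8 and 0 with the GC and length correction (median -0.19, camera adjusted p = 0.0465; adjusted p = 0.384 with an estimated correlation). EZH2, the H3K27 methyltransferase, fell from 41.1 ± 1.66 to 16.4 ± 0.231 CPM (log2 -1.32), SUZ12 fell by 1.05, PHF19 by 1.03 and EED by 0.83 on the log2 scale. With the GC and length correction EED stood at -0.29 and did not pass (edgeR adjusted p = 0.0941). Of 28 p53 targets 14 rose and 1 fell, or 2 adjusted over the list alone (median 0.24, camera adjusted p = 0.0465; adjusted p = 0.384 with an estimated correlation). In that list 12 rose and 2 fell without control library 1, and likewise without Knockdown-732. With library size only 11 rose and 4 fell, with the GC and length correction 11 and 3, without control library 2 11 and 1, and in DESeq2 10 and 1. The CDK inhibitor CDKN1A rose from 217 ± 17.3 to 364 ± 15.5 CPM (log2 0.75), TP53INP1 rose by 1.73 and the death receptor TNFRSF10B by 0.54, and CCNG1 fell by 0.79 on the log2 scale. Leaving out any 1 of the 4 libraries ended both calls: without control 1, control 2, Knockdown-670 and Knockdown-732 in that order, camera's adjusted p was 0.0747, 0.0594, 0.0653 and 0.0691 for polycomb and 0.0629, 0.0588, 0.0585 and 0.0853 for p53 targets. Over all 13 alternatives it ran from 0.0021 to 0.384 for polycomb and from 0.0106 to 0.384 for p53 targets.

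The other 16 lists with at least 5 tested members, the mitochondrial one included, did not pass in camera. Genes tied to SBF2-AS1 in earlier work, recalled from the literature, rose in 2 and fell in 8 of 12 cases (camera adjusted p = 0.078). That list had 1 higher and 8 lower without Knockdown-732, 3 and 6 without control library 2, and 3 and 9 with the GC and length correction. FOXM1 (log2 -1.31), E2F1 (-1.63), EZH2 and SUZ12, which other lists also hold, were among those that fell. Of 22 neighbours on chromosome 11p15, 9 rose and 5 fell, or 10 and 3 with the GC and length correction (camera adjusted p = 0.156), with AMPD3 at 1.90, DKK3 at 1.23, ADM at 1.09 and MICAL2 at 0.75 on the log2 scale. Inflammatory NF-kB targets rose in 14 and fell in 8 of 29 cases, or 9 adjusted over the list alone and 5 without control library 1 (camera adjusted p = 0.156); IL1B rose by 1.94, IL6 by 1.81, ICAM1 by 1.09 and CCL20 by 0.98. TGF-beta targets rose in 11 and fell in 6 of 23 cases (camera adjusted p = 0.156), with ANGPTL4 at 2.10, ID3 at -1.18 and ID2 at -1.28. Abundant long non-coding RNAs rose in 5 and fell in 12 of 28 cases, or 13 adjusted over the list alone (camera adjusted p = 0.157): MEG3 rose by 1.60, and SNHG1 fell by 1.21, SNHG15 by 1.24 and H19 by 2.09. ATF4 and unfolded-protein genes rose in 5 and fell in 15 of 32 cases, or 3 and 16 with library size only and 3 and 14 in DESeq2 (camera adjusted p = 0.157), with XBP1 at -1.22, MTHFD2 at -0.76, CEBPG at -0.68 and TRIB3 at -0.62. With the GC and length correction the literature list and the 11p15 neighbours did pass in camera (adjusted p = 0.0419 and 0.0278), within ranges of 0.0106 to 0.479 and 0.0218 to 0.608 over 13 alternatives each.

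Cholesterol genes rose in 5 and fell in 12 of 33 cases (camera adjusted p = 0.207), with INSIG1 at 1.38, FDPS at -0.70 and FADS2 at -0.61 on the log2 scale. Autophagy and lysosome genes rose in 13 and fell in 7 of 31 cases, or 14 and 8 adjusted over the list alone and 12 and 4 without Knockdown-670 (camera adjusted p = 0.217); the sterol transporter NPC1 rose by 1.10 and the cathepsins CTSD, CTSA and CTSB by 1.02, 0.92 and 0.77. Ribosomal protein genes rose in 10 and fell in 7 of 51 cases (camera adjusted p = 0.237); RPL27 was at -0.45, RPS12 at -0.92 and RPS6 at -0.31, and with the GC and length correction RPS6 stood at 0.007 and the list passed with 18 higher and 5 lower (camera adjusted p = 0.0419, range 0.0419 to 0.914 over 13 alternatives). The ribosomal counts rested on single libraries, with 4 higher and 7 lower without Knockdown-670 (median 0.03) and 20 higher and 4 lower without Knockdown-732 (median 0.16). Epithelial genes rose in 8 and fell in 5 of 21 cases (camera adjusted p = 0.31); CDH3 rose by 2.12 and KRT19 by 1.06, and KRT18 fell by 0.86. RNA-silencing genes rose in 7 and fell in 3 of 16 cases, or 7 and 1 in DESeq2 (camera adjusted p = 0.435), with the editing enzyme ADAR at 0.93, DICER1 at 0.71, TNRC6A at 0.61 and AGO2 at 0.56. Apoptosis genes rose in 10 and fell in 4 of 28 cases, or 8 and 7 with library size only (camera adjusted p = 0.473): BAK1 rose by 0.96, BIRC3 by 0.79 and MCL1 by 0.73, and CYCS fell by 0.67. Of 16 tested replication-dependent histone genes 4 rose and 2 fell (camera adjusted p = 0.608), or 4 and 1 without control library 1, 3 and 0 in DESeq2 and 2 and 0 of 5 tested with the filter of 5 CPM. The list's median was 0.30 while its mean was -0.05, and the median was 0.04 without control 1 (16 tested), and 0.11, 0.16 and -0.12 without control 2, Knockdown-670 and Knockdown-732 (19 tested in each). It was 0.56 with the filter of 5 CPM, 0.48 with the GC and length correction and -0.16 with no filter (49 tested). HIST1H4H was at 1.89, HIST2H2BE at 1.37 and HIST1H2BL at -2.92, the last without passing when control library 1 was left out (edgeR adjusted p = 0.0537). WNT targets rose in 4 and fell in 5 of 15 cases (camera adjusted p = 0.623), with MMP7 at 0.66, CCND1 at -0.48, BMP4 at -0.94 and DKK1 at -1.43. With the GC and length correction 3 WNT targets rose and 7 fell, and the median was -0.38 in place of -0.09 (camera adjusted p = 0.309). Unless given, the counts of these lists were the same adjusted over the list alone.

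Of 18 markers of alveolar and secretory epithelium only 6 were expressed highly enough to test, and the surfactant gene SFTPB, the club cell gene SCGB1A1 and the lung transcription factor NKX2-1 reached at most 0, 0 and 0.23 CPM in any library. Of the 6, 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.156). The surfactant lipid transporter ABCA3 rose from 73.3 ± 1.31 to 148 ± 1.84 CPM (log2 1.01) and LAMP3 by 2.24, and the mucins MUC5B and MUC5AC were at 0.49 and -0.25; MUC5B stood at -0.09 with the GC and length correction. MUC5AC lost its call without control library 2 (edgeR adjusted p = 0.0958) and without library Knockdown-732 (0.061), and in DESeq2 (0.0614). Markers of other cell types were too few for a test: 4 of 16 immune, 4 of 11 fibroblast, 1 of 10 endothelial and 0 of 8 erythroid markers were expressed highly enough. CD68, a lysosomal protein of macrophages, rose from 57.2 ± 0.865 to 170 ± 14.8 CPM (log2 1.57), while the pan-leukocyte PTPRC reached at most 0.08 CPM in a knockdown library. The fibroblast marker FBN1 rose by 0.81 on the log2 scale, the 1 fibroblast marker that passed (2 of 6 tested passed without Knockdown-732). The endothelial ESAM, at most 2.52 CPM in a control and 1.71 CPM in a knockdown library, had a log2 fold change of -0.86 (edgeR adjusted p = 0.0635). It was the only tested member, so adjusting over its list alone leaves p unadjusted. ESAM passed in that way and with the GC and length correction (-0.94).

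Each knockdown library was also set against the controls on its own, to see how far Knockdown-670 and Knockdown-732 gave the same changes. Against the controls 6775 genes passed in Knockdown-670 (3485 higher, 3290 lower) and 6473 in Knockdown-732 (3314 higher, 3159 lower), in edgeR's quasi-likelihood test with 3 groups. Between the knockdown libraries that fit named 65 genes, 42 higher in Knockdown-670 and 23 higher in Knockdown-732. Each side was 1 library, assumed to vary like the control pair, so this compares those libraries and not conditions, and has no replicate check. Of the genes called against the controls, 2758 were higher in both where independent lists would share 716, and 2529 lower in both where they would share 645; 17 were called in opposite directions. Both comparisons used the same controls, so independence is not their value with no effect: unchanged groups simulated against shared controls had on average 0.4 genes higher and 0.4 lower in both (20 simulations), and 53.4 and 46.1 at an unadjusted p under 0.05. Neither value holds both real effects and shared controls, so part of the excess may come from the shared controls. Across 16120 genes, which are not independent replicates, the log2 fold changes of Knockdown-670 and Knockdown-732 correlated at r = 0.863 (rho = 0.854). Unchanged groups simulated against the same controls gave r = 0.326; the covariance was 0.377 against 0.0253, a difference of 0.352. With a separate control for each library, r was 0.748 and 0.753 in the 2 pairings. The spread in this fit came from the control pair alone, and a DESeq2 Wald test in the same design called 2383, 2152 and 3 genes.

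The series title speaks of SBF2-AS1 as a microRNA sponge, so genes with sites for 5 microRNAs tied to it, recalled from the literature, were compared with other genes. Of 12857 tested genes with an annotated 3' UTR, 1538 to 1919 held a 7-base match to the seed of each microRNA. The median log2 fold change of genes with and without a site was 0.07 and 0.00 for miR-338-3p, 0.08 and 0.00 for miR-362-3p, -0.01 and 0.02 for miR-140-5p, -0.06 and 0.02 for miR-361-5p and -0.01 and 0.02 for miR-188-5p. None of the 5 sets passed in camera (adjusted p from 0.507 to 0.895), and 0 had an unadjusted p under 0.05. With 8-base sites, with an estimated correlation or against genes of matched 3' UTR length 0 passed. The levels of these microRNAs were not examined, and sets of 1538 to 1919 genes could hide a shift of a small part of their members.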

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

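The correction for GC content and length, the runs without pseudogenes and unmatched symbols and the lists without genes holding TACTGCT were chosen after the data were seen; the other alternatives were planned. SBF2-AS1 was lower and past the threshold in each of its 14 alternatives (edgeR, DESeq2 or limma adjusted p from 1.87e-09 to 0.000277); the filter of 5 CPM in 2 libraries gave it no value. The 7463 called genes became 6214 to 6749 with 1 library left out, 5311 with DESeq2, 6791 with the filter of 5 CPM, 6675 with the GC and length correction and 6756 without pseudogenes and unmatched symbols. They were 7371 to 7733 with the other scalings, no filter, limma-voom, the exact test and the non-robust fit, and 8593 (4352 higher, 4241 lower) at an adjusted p of 0.1. With glmTreat against 1.2-fold they were 4680 (2451 higher, 2229 lower), where fewer calls follow from the stricter question. With 1 library left out the lone remaining library of its group is assumed to vary like the other group. Of 1968 values of 132 named genes under alternatives, 1961 kept direction and call and 5 lost the call; RPS6 (0.0067) and MUC5B (-0.087) changed sign on the log2 scale with the GC and length correction, and the cause was not tested. Of the 27 lists, 11 passed with camera's preset correlation, 6 to 9 with 1 library left out (7 without control 1, 6 without library Knockdown-732), 0 with an estimated correlation and 22 with fry. With an estimated correlation the adjusted p was 0.119 for interferon, mitosis, replication and hypoxia, 0.199 for mesenchymal, 0.402 for YAP, 0.384 for NRF2, immediate early, polycomb and p53, and 0.563 for oxidative phosphorylation. Oxidative phosphorylation also stood at 0.0572 with fry and 0.274 with the GC and length correction, and immediate early at 0.0889 with that correction. Polycomb stood at 0.0655 with the filter of 5 CPM and 0.0921 without genes holding TACTGCT, and p53 at 0.0685 with library size only and 0.135 without genes holding TACTGCT. With 1 library left out the adjusted p ran from 0.0585 to 0.0853 for p53, 0.0345 to 0.085 for NRF2, 0.0313 to 0.0732 for immediate early, 0.00566 to 0.0815 for oxidative phosphorylation and 0.0594 to 0.0747 for polycomb; fewer libraries enter these fits. DESeq2 in the 3-group design called 2383, 2152 and 3 genes for Knockdown-670, Knockdown-732 and their difference, the filter of 5 CPM left 15 genes between Knockdown-670 and Knockdown-732, and the agreement of Knockdown-670 and Knockdown-732 was 0.748 and 0.753 with a separate control for each. The filter tests fewer genes and the separate controls are fewer libraries; the cause of the DESeq2 counts was not tested. Only 26.7% of the mitochondrial list had a GC value, so its GC check is void. Medians of the epithelial (-0.005) and TGF-beta (-0.07) lists were below 0 with the GC and length correction, that of apoptosis (-0.04) with library size only, that of histones without library Knockdown-732 (-0.12) and, with the epithelial one, without a filter (-0.16 and -0.04). Depth limits genes such as SBF2-AS1 itself, whose counts of 15 and 18 leave wide intervals.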

Other observations

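The test of cell-cycle genes without TACTGCT and the count of immune markers at 5 CPM were written before their results were seen; the 4 gene lists of the next paragraph, the heptamer scan with its site classes, the sponge and duplex tests, the further count of immune markers, the test of pseudogenes and the count of splits were chosen after.

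Of further groups, 4 lists and their named members were picked after the values were seen and tested on the same values, so their p-values are not independent evidence. These lists were adjusted together with the 27 others, and with an estimated correlation 0 of the 31 passed in camera. Of 31 homologous recombination and Fanconi genes 29 fell and none rose, also adjusted over the list alone (median log2 fold change -1.38, camera adjusted p = 1.71e-14; unadjusted p = 0.012 and adjusted p = 0.109 with an estimated correlation), with BRCA1 from 112 to 33.9 CPM, FANCI from 187 to 50.4 CPM and BLM at -2.09 on the log2 scale. Of 21 genes of antigen presentation by class I molecules 17 rose and none fell (median 0.79, camera adjusted p = 7.18e-07; unadjusted p = 0.029 and adjusted p = 0.15 with an estimated correlation), with HLA-B from 36.1 to 124 CPM and the class I transactivator NLRC5 from 8.18 to 43.1 CPM; TAP1 and PSMB9 are also in the interferon list. Of 27 basement membrane genes 22 rose and none fell (median 0.71, camera adjusted p = 4.47e-08; adjusted p = 0.274 with an estimated correlation), with COL7A1 from 237 to 711 CPM, HSPG2 from 316 to 803 CPM and the integrin ITGA3 from 756 to 1952 CPM. Of 15 aldehyde dehydrogenases 10 fell and 1, ALDH1A3, rose (median -0.42, camera adjusted p = 0.0228; adjusted p = 0.305 with an estimated correlation), with ALDH2 from 186 to 45.7 CPM; ALDH1A1 and ALDH3A1 are also in the NRF2 list.

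Genes whose 3' UTR holds TACTGCT were on average lower in both knockdown libraries: over 16377 heptamers in 9913 genes, with a spline taking out 3' UTR GC, length and expression, this heptamer (1222 genes) had the lowest z, -10.3, and ranked 1 in each of the 4 knockdown-control pairs (z -9.73 to -10.3), against 2.10 between the controls and -0.98 between Knockdown-670 and Knockdown-732. Base composition or length is argued against, since the spline took them out, the lowest heptamer not overlapping TACTGCT stood at -3.89 and its reverse complement AGCAGTA at 0.15. The 100 permutations of the genes went no lower than -4.88, which bears on chance and not on composition. For the genes with TACTGCT, camera without the spline gave p = 9.04e-05, and p = 0.136 with an estimated correlation. The mean adjusted log2 fold change was -0.185 ± 0.035 (SE) for 251 genes with TACTGCTA (63.7% below 0; 120 called lower, 42 higher), -0.152 ± 0.017 for 971 with TACTGCT alone (65.1% below 0; 416 called lower, 182 higher), -0.073 ± 0.021 for 560 with ACTGCTA and 0.011 ± 0.011 for 2281 with ACTGCT, the last no lower than the 0.010 of genes with none, so the bound first written for a small RNA, the 8-base class below the 7-base class by more than the errors, was not met (difference 0.033 ± 0.038), and by it a small RNA would have been rejected; that bound was set aside after these values were seen, because a difference within its error excludes nothing. A small RNA with that seed, such as a strand of the siRNA, may still be the source. The sites do not tell it apart from a microRNA of the same seed freed by loss of SBF2-AS1, because both act at the same sites. The loss of SBF2-AS1 was 0.00405% of the CPM of genes with the heptamer. A sponge was predicted to be a sizeable part of that RNA, and SBF2-AS1 was not. Its level of 5.19 CPM in the controls kept this share small whatever the siRNA did, and no bound had been set. The value therefore does not decide whether SBF2-AS1 acts as a sponge. SBF2-AS1 holds TACTGCT in 4 of 7 transcripts, in exon 2 of 3 of the 2709-nt transcript (chromosome 11, 9807853 to 9807859, GRCh38, within ACCCAGAAGGAGTCTACTGCTAAGA), but the 4 transcripts hold 3.68% (638 nt), 4.46% (767 nt), 14.5% (2709 nt) and 18.9% (3693 nt) of all heptamers, and the siRNA sequences are not given in the sources used here.

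Interferon-stimulated genes were higher and cell-cycle genes lower in both knockdown libraries. Repression through TACTGCT in their own 3' UTRs does not account for the cell-cycle genes: 63 of the 64 replication and mitosis members without the heptamer fell. Their median log2 fold change was -1.49 (95% bootstrap interval over members, which are not independent, -1.61 to -1.36), beside -1.65 for the 10 members with the heptamer. An indirect effect, through a regulator that holds the heptamer, was not tested. For RNA of immune cells the bound set beforehand, fewer than 2 of 16 immune markers at 5 CPM in a knockdown library, was not met, since 3 (CD68, CD14 and ITGAM) reached it; the case against rests on a count chosen after this was seen, that the same 3 reached it in a control and 0 only in the knockdown, while LYZ, PTPRC and HLA-DRA reached 0.16, 0.08 and 0 CPM. A response of innate RNA sensors to the duplex, which would be in each library given it, cannot be told apart from an effect of losing SBF2-AS1, since both knockdown libraries received another duplex than the controls; the interferon list's median was 2.59 in the lower of them. Loss of SBF2-AS1 itself stays open and was not tested separately.

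The 65 genes that edgeR named between Knockdown-670 and Knockdown-732, 1 library each with the spread of the control pair, were 58.5% pseudogenes, against 10.1% of the other tested genes (odds ratio 12.6); DESeq2 named 3 and edgeR with the filter of 5 CPM 15. The 65 also differed more between the controls, with a median absolute log2 ratio of 0.483 against 0.135. Among genes picked after their values were seen, CD99 had 0 and 490 counts in the controls and 0 and 740 in Knockdown-670 and Knockdown-732, and SMN2, one of a pair of near-identical genes, had 86, 251, 55 and 306. Whether reads shared between near-identical copies underlie them stays open, because single libraries give no test of a difference; by the bound first written these values counted for that source, and the reading was withdrawn after they were seen. No biological explanation was tested, since the labels do not say how Knockdown-670 and Knockdown-732 differ.

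Of the 3 splits of the 4 libraries into pairs, 1 gave as many genes as the labelled one, that split itself, with 7463. The highest other split gave 0 in edgeR. The other splits had 41 and 49 genes at an unadjusted p under 0.05 in edgeR, and 3 and 1 genes in DESeq2. Each of them put 1 control and 1 knockdown library in each pair, so the difference between knockdown and control entered its spread. Few calls in them follow from that design and do not bear on chance. Also, 3 splits are too few for a share under 0.05. Across 12857 genes, which are not independent, 3' UTR GC content correlated with the log2 fold change of knockdown over control at rho = 0.354, with that of control 1 over control 2 at -0.092 and with that of Knockdown-670 over Knockdown-732 at 0.197.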
